A study of Oryza sativa with 156 samples.

How the data were processed

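Leaf polyA RNA was sequenced from 156 samples of rice (IR64), in libraries made with a strand-preserving kit, per the labels' protocols. The deposited values are raw read counts per gene, 1 table for the whole series. The reads were aligned with STAR and counted with featureCounts 2.0.0 on the build IRGSP-1.0, per the submitters' processing notes. The strand setting, the treatment of reads that match several genes and the STAR version are not given in the sources used here. Genes that overlap, lie on opposite strands or have near-identical copies can therefore share counts.

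The count table holds 55986 identifiers, 55801 of them of the LOC_Os form. The table of gene names at hand (assembly ASM3414082v1) matched 0 of them, so no names, coordinates or annotation are given. The 16 lists by locus and 12 by product name that were fixed beforehand could not be placed on these identifiers, with 0 of 215 loci found, so the planned gene list shifts (camera) were not run. Columns were assigned to samples by name, 4 columns that match no sample were not used, and no 2 columns were identical. Total counts per library ranged from 6.42 to 26.2 M. Pairs of libraries differed by a chi-square per gene of at least 7.51 within groups and 6.26 between groups.

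All tests were made on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 19338, and libraries were scaled by TMM. A quasi-likelihood model (glmQLFit, glmQLFTest) with 52 groups of course, arm and day was fitted to all libraries, with 104 residual degrees of freedom. Contrasts were the mean over the days of drought minus control, for day 0, days 1-4, days 5-8, days 9-12 and each day, and the severe minus moderate difference of these. Adjusted p is by Benjamini and Hochberg over all genes tested with a threshold of 0.05, "called" means an adjusted p below it, and "rose" and "fell" stand for higher and lower in drought than in control. Standard errors were taken as the absolute log2 fold change over the square root of F. CPM values use the TMM-scaled totals, and log2 CPM has a prior count of 2.

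The genes named are those with the largest change among genes called, with a mean log2 CPM of at least 1 and the same sign on each of the 4 days, 8 in each direction for days 5-8 and days 9-12 of a course and 6 for the severity contrasts, fixed before the data were examined. The rule was extended to days 1-4 afterwards. Scores used genes with a mean log2 CPM of at least 3, and their permutation test drew 100000 shuffles of the arms within each day.

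Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, edgeR or DESeq2 1.42.0 on the libraries compared only, a replicate block, a replicate block within day, leaving out each replicate number, and a 2-fold minimum. Alternatives added after the data were examined were counts thinned to 6.42 M per library, dispersions estimated beforehand, the adjustment for the library set, days 3-4 or day 5 alone, edgeR and DESeq2 on the libraries of days 3-5, days 3-4 and day 5 only, and leaving out single doubted libraries. The contrasts of days 3-5 and of days 9-12 minus days 1-4 were added then too. The rule for reading the slopes of the library set difference was also set then and was changed: both estimates under 0.25 is taken to argue against the set, and a rule used in between, which also asked that the calls left after adjusting stay within 1.5 times, left the set open for the genes other than the 235.

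The methods were tested on simulated data with 200 genes changed in severe drought on days 9-12 and another 200 genes raised 4-fold in the higher library set. In the contrast of severe drought on days 9-12, with 18799 genes run, 77 of the 94 genes tested with a 1.5-fold change and 86 of the 96 with a 2-fold change were recovered, and 26 of 18409 unchanged genes were called. In the same contrast with the library set taken out, 47 of 94 and 70 of 96 were recovered, and 0 of the 200 set genes were called, against 196 without the adjustment. The simulated data held no change over the days and no other drought change. In the real data such changes can enter the estimate of the set difference. The simulation therefore does not show how cleanly the adjustment removes the set from the real data.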

Results

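Leaf RNA of the rice cultivar IR64 was sequenced each day from day 0 to day 12 while pots dried, in 2 courses with their own irrigated controls. In the moderate course the water supply was stopped 14 days after sowing and the water drained through the hose of each pot. In the severe course the pots were also raised above the hose, so that they drained faster. Each of the 52 combinations of course, arm and day held 3 libraries. Each arm of a course had 39 libraries, and total counts, in mega counts (M), ranged from 6.42 to 26.2 M with a median of 16.8 M. The median total was 18.3 M in moderate control, 17.8 M in moderate drought, 12.3 M in severe control and 15.2 M in severe drought. The series title names biomarker genes for levels of drought perception as its purpose, so the comparisons ask which genes differed between drought and control, when, and whether the courses differed. The labels do not say whether the replicates came from separate plants, so p-values measure the spread between these samples. Genes are given by the identifiers of the count table, which the files do not pair with names, and at most 2 rising and 2 falling identifiers are given per comparison. Levels are given in counts per mega count of the library (CPM) as means ± SD over the 12 libraries of an arm in a stretch of 4 days, so that the SD includes change from day to day.

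In the moderate course, 8214 of 19338 genes differed between drought and control on days 1-4, of which 4071 rose and 4143 fell. LOC_Os03g54130 rose from 19.2 ± 13.3 to 173 ± 70.1 CPM (SD, n = 12; log2 fold change 3.14, SE 0.39, adjusted p = 7.8e-11). LOC_Os09g36680 fell from 1850 ± 1870 to 31.3 ± 26.4 CPM (SD, n = 12; log2 fold change -5.51, SE 0.88, adjusted p = 1.9e-07). LOC_Os03g14910 rose with a log2 fold change of 2.58 and LOC_Os09g36700 fell with -5.38, and these 4 genes were chosen after their values were seen. Most changes were small, and 770 of the 8214 genes changed at least 2-fold. The number of genes called fell to 5553 on days 5-8, with 2745 higher and 2808 lower in drought, and was 2971 to 4252 without 1 replicate number.

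On days 5-8 of the moderate course LOC_Os05g33900 rose from 4.36 ± 2.49 to 44.6 ± 28.9 CPM (SD, n = 12; log2 fold change 3.41, SE 0.4, adjusted p = 1e-10). LOC_Os03g30420 rose with a log2 fold change of 2.88. LOC_Os09g36700 fell from 40.6 ± 50.7 to 1.66 ± 1.78 CPM (SD, n = 12; log2 fold change -4.87, SE 0.82, adjusted p = 1.8e-06), and LOC_Os09g36680 fell with -4.07. On days 9-12, 2381 genes rose and 2243 fell, 4624 in all, or 2611 to 3060 genes without 1 replicate number. LOC_Os02g15860 rose from 0.81 ± 0.722 to 7.62 ± 6.24 CPM (SD, n = 12; log2 fold change 3.31, SE 0.35, adjusted p = 1.2e-12), and LOC_Os09g26670 rose with a log2 fold change of 2.15. LOC_Os01g72370 fell from 136 ± 217 to 5.58 ± 7.12 CPM (SD, n = 12; log2 fold change -4.23, SE 0.97, adjusted p = 0.00048). The same stretch had LOC_Os09g36700 falling with a log2 fold change of -4.41. The 8 risers and 8 fallers that the naming rule took on these days had log2 fold changes from 2.02 to 3.31 and from -2.31 to -4.41.

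**Figure D1:**
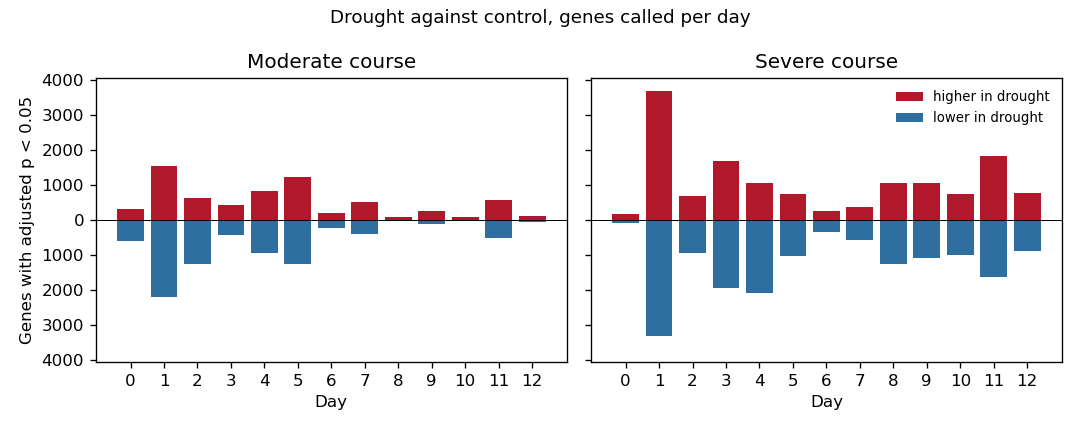
Number of genes with an adjusted p under 0.05 between drought and control (vertical axis) on each day (horizontal axis), with genes higher in drought above 0 and genes lower in drought below 0, for the moderate course (left) and the severe course (right). The highest count in each course stands on day 1, with 3743 genes in the moderate and 7012 in the severe course.

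In the severe course, 9165 genes differed on days 1-4, of which 4516 rose and 4649 fell, and 1344 changed at least 2-fold. LOC_Os03g54130 rose from 10.2 ± 9.09 to 107 ± 43.4 CPM (SD, n = 12; log2 fold change 3.69, SE 0.42, adjusted p = 1.5e-12). LOC_Os05g11320 rose with a log2 fold change of 3.96 and LOC_Os09g36680 fell with -5.12. LOC_Os09g36700 fell with a log2 fold change of -4.82, a call that ended without replicate 2 (adjusted p = 0.077). The genes named for days 1-4 were chosen after their values were seen. On days 5-8, 2717 genes rose and 2796 fell, 5513 in all, or 2213 to 6214 without 1 replicate number and 3492 by edgeR on the libraries compared only. LOC_Os01g47370 rose from 2.86 ± 1.74 to 34.4 ± 27.5 CPM (SD, n = 12; log2 fold change 3.55, SE 0.45, adjusted p = 7.6e-10), LOC_Os05g33900 rose with a log2 fold change of 3.1, LOC_Os01g72370 fell with -6.08 and LOC_Os09g36680 fell with -5.47.

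On days 9-12 of the severe course 4248 genes rose and 4394 fell, 8642 in all, or 5465 to 7403 without 1 replicate number. LOC_Os09g36680 fell from 881 ± 695 to 7.89 ± 7.61 CPM (SD, n = 12; log2 fold change -6.8, SE 0.95, adjusted p = 4.4e-09). LOC_Os01g03340 fell from 19.5 ± 15.1 to 0.554 ± 0.516 CPM (SD, n = 12; log2 fold change -5.13, SE 0.64, adjusted p = 1e-10). LOC_Os01g47370 rose with a log2 fold change of 3.46 and LOC_Os09g26670 with 2.8. Among the 1227 genes that changed at least 2-fold, 867 fell. With the library set taken out, 5 of the 8 fallers and 8 of the 8 risers taken by the naming rule were still called.

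The libraries of the severe course fell into 2 sets that followed arm and day. The mean log2 CPM of 3 genes, LOC_Os01g57960, LOC_Os01g49370 and LOC_Os06g39708, lay at 6.15 or above in 49 libraries and at 5.35 or below in the other 107. The higher set held the severe control libraries of days 3 to 12, the severe drought libraries of days 0 to 5 and 1 moderate drought library of day 0. LOC_Os01g57960 stood at 300.0 ± 54.8 CPM in the higher set (SD, n = 49) and at 29.7 ± 10.9 CPM in the lower set (SD, n = 107). The arms of the severe course therefore lay in different sets on days 0 to 2 and 6 to 12, and in the same set on days 3 to 5. On days 3-5 of the severe course 3498 genes rose and 4123 fell, 7621 in all. The difference between the sets was estimated from the change of severe controls between days 0-2 and 3-5 and of severe drought libraries between days 3-5 and 6-8, each beyond the moderate course. With its mean taken out, 8191 genes were called on days 1-4, 4384 on days 5-8 and 4403 on days 9-12. Genes called with at least a 2-fold change on days 9-12 numbered 1227 before and 904 after. The adjustment adds the spread of the estimate, and in the simulation it lowered the recovery of 1.5-fold changes from 77 to 47 of 94. A lower count with the set taken out, here and below, is therefore not a count of genes owed to the set. Across genes the estimates from controls and from drought libraries correlated with r = 0.2, and they called 1613 and 126 genes. Both called 49 genes higher in the higher set, against 6 for independent lists. Each estimate also holds any change over the days particular to the severe course. On days 5-8 the adjustment also cancels part of the weight of the drought libraries of days 6-8. On days 1-4 it cancels part of the weight of the controls of days 1 and 2 and of the drought libraries of days 3 and 4.

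**Figure D2:**
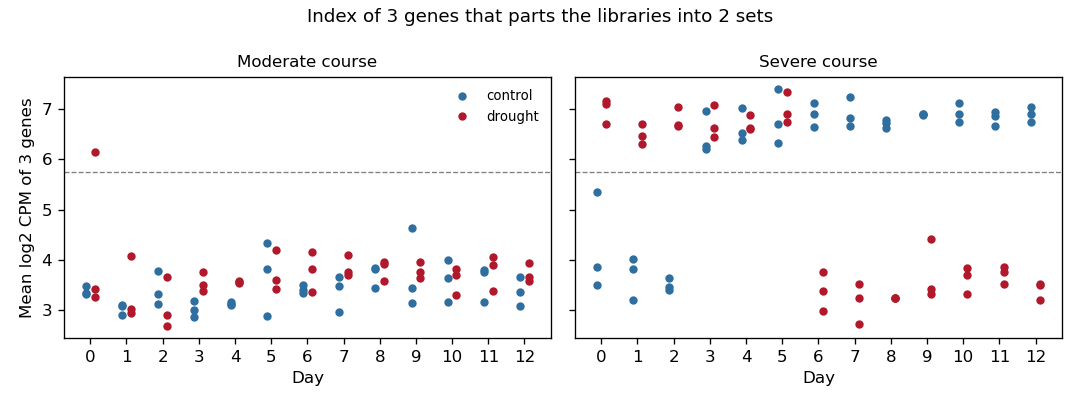
Mean log2 CPM of the 3 genes LOC_Os01g57960, LOC_Os01g49370 and LOC_Os06g39708 (vertical axis) in each library by day (horizontal axis), for the moderate course (left) and the severe course (right), with control libraries in blue and drought libraries in red. The dashed line lies midway in the gap between 5.35 and 6.15, and 49 libraries lie above it.

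Genes that rose or fell in every stretch of both courses numbered 404 and 387, against 0.5 and 0.6 for independent lists. LOC_Os02g15860 and LOC_Os03g30410 had the largest rise in their weakest stretch among them, and LOC_Os09g36700 and LOC_Os09g36680 the largest fall, and these 4 were chosen after their values were seen. All 4 kept the sign of their change on each of the 24 day contrasts from day 1 to day 12. The weakest log2 fold change of LOC_Os02g15860 was 2.03 and that of LOC_Os03g30410 was 1.86. That of LOC_Os09g36700 was -4.41 and that of LOC_Os09g36680 was -4.04. In severe drought on days 9-12 LOC_Os09g36700 stood at 0.031 ± 0.0335 CPM (SD, n = 12) against 15 ± 14.1 CPM in control (SD, n = 12), so that its fold change there rests on few counts. In the 4 contrasts whose arms share a library set, which are the moderate stretches and days 3-5 of the severe course, 735 genes rose and 658 fell throughout. These lists shared 385 risers and 369 fallers with the lists from all 6 stretches. The identifiers LOC_Os09g36680 and LOC_Os09g36700 are close in number, and whether their reads can be told apart was not analysed here.

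**Figure D3:**
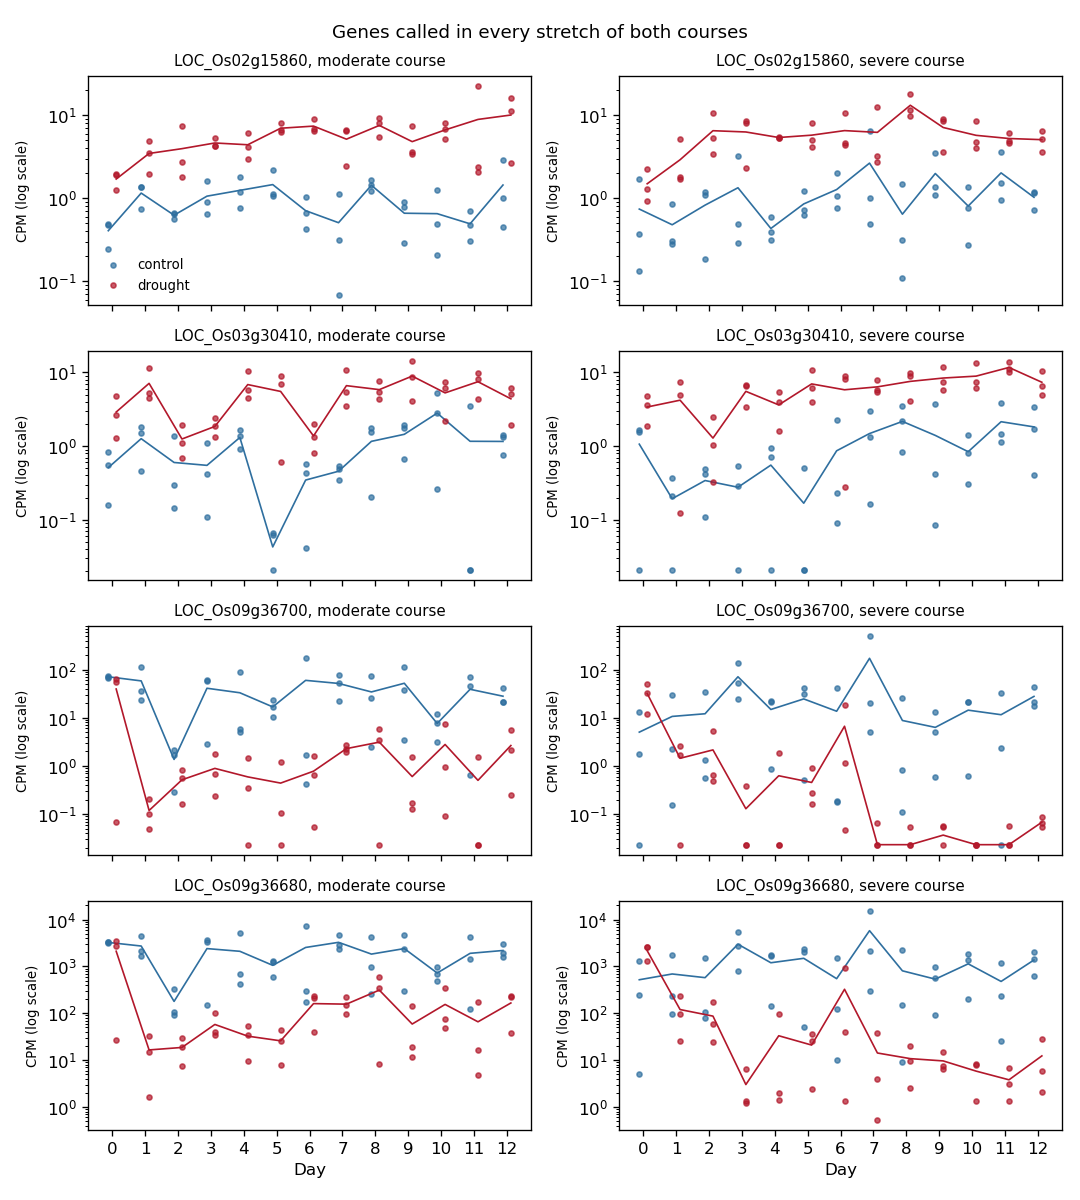
CPM on a log scale (vertical axes) by day (horizontal axes) of 4 genes called in every stretch, in the moderate course (left) and the severe course (right), with libraries as points and the mean of 3 libraries as lines, control in blue and drought in red; values of 0 are drawn at 0.5 times the lowest value above 0 of that gene. LOC_Os09g36680 stood at 1810 ± 1480 CPM in moderate control and 111 ± 111 CPM in moderate drought on days 9-12 (SD, n = 12).

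The courses shared much of their response. On days 1-4, 2807 genes rose and 3164 fell in both, where independent lists would share 951 and 996. On days 5-8, 1408 rose and 1519 fell in both, against 386 and 406 expected. On days 9-12, 1430 rose and 1470 fell in both, 2900 in all against 1033 expected, and 62 genes were called in opposite directions. Leaving out 1 replicate number left 1367 to 1832 shared calls on these days. Across genes, which are not independent replicates, the fold changes of the courses correlated with r = 0.74 on days 1-4, 0.67 on days 5-8 and 0.60 on days 9-12. On days 3-5, where both courses can be compared within library sets, r was 0.68, with 1907 shared risers and 2234 shared fallers. The courses have their own controls, so no library entered both sides. With the library set taken out of the severe contrast, 1678 calls were shared on days 9-12.

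Many genes differed between the early and late responses. In the severe course 1098 genes rose and 1183 fell in both stretches, against 992 and 1056 expected, while 980 rose on days 1-4 and fell on days 9-12 and 1196 did the reverse, against 1026 and 1021 expected. Its arms changed library sets between the stretches, and with the set taken out 337 and 630 genes were called in such opposite directions, against 406 and 530 expected. Between days 3-5 and days 9-12 with the set taken out these were 148 and 264, against 379 and 492. The fold changes of days 1-4 and 9-12 correlated across genes with r = 0.12, and those of days 3-5 and 9-12 with 0.39 (0.34 with the set taken out of days 9-12). In the moderate course 82 genes rose early and fell late and 102 did the reverse, against 472 and 510 expected, while 1289 rose and 1010 fell in both, against 501 and 481 expected, and r was 0.50, or 0.55 between days 3-5 and 9-12. The test of the difference itself, days 9-12 minus days 1-4, called 8460 genes in the severe and 3801 in the moderate course. Without 1 replicate number it called 5228 to 7481 and 1600 to 2785. Across genes these late minus early differences correlated between the courses with r = 0.59. Further, 990 moderate genes rose early, were not called late and moved down between the stretches, and 1602 fell early, were not called late and moved up. With the library set taken out, 4171 genes differed between the stretches in the severe course.

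The severe minus moderate difference was called for 80 genes on days 1-4, 21 higher and 59 lower, and for 103 genes on days 5-8, 9 higher and 94 lower. After the library set was taken out these were 189 genes, 15 higher and 174 lower, and 65 genes, 20 higher and 45 lower. On days 1-4 they were 264 or 23 with the set difference from controls or from drought libraries alone, and leaving out a replicate number, with no adjustment, left 6 to 56 genes. The estimate from controls cancels most of the weight of the controls of days 1 and 2. The estimate from drought libraries cancels most of that of the drought libraries of days 3 and 4 and brings in days 6-8. The 264, the 23 and in part the 189 thus set different days against each other. On days 5-8 they were 135 or 48, and 45 to 104 without 1 replicate number and with no adjustment. There the estimate from drought libraries cancels the drought libraries of days 6-8, so its 48 sets drought of days 3-5 against controls of days 5-8. The mean estimate, which gave 65, cancels them in part. On days 9-12 the severe minus moderate difference was called for 2127 genes, of which 1129 were higher and 998 lower, and of the 291 that differed at least 2-fold 235 were lower. LOC_Os01g49370 had 71.8 ± 7.02 CPM in severe control (SD, n = 12), 5.55 ± 1.59 in severe drought, 5.36 ± 2.14 in moderate control and 5.18 ± 1.09 in moderate drought on days 9-12 (log2 difference -3.67, SE 0.28, adjusted p = 2.1e-20), and with the library set taken out its difference turned to 0.35 (adjusted p = 0.63). LOC_Os01g57960 had a log2 difference of -3.57, and both genes mark the library sets. LOC_Os07g48170 and LOC_Os06g37010 were higher, with log2 differences of 3.03 (SE 0.91, adjusted p = 0.019) and 1.84 (SE 0.6, adjusted p = 0.034), and both calls ended without replicate 2 and with the library set taken out. With the set taken out 612 genes differed on days 9-12, or 1303 and 11 with the set difference estimated from controls or from drought libraries alone, and without replicate 2 182 did. Within library sets 434 genes differed between the courses on days 3-5, 74 higher and 360 lower, and 679 on days 3-4, while the same edgeR model called 0 on day 5 alone (1218 at an unadjusted p under 0.05, DESeq2 on the libraries compared only 0). On the libraries compared only, edgeR called 22 and DESeq2 241 on days 3-5, and 12 and 541 on days 3-4.

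The calls also differed by day. In the moderate course they numbered 3743 on day 1, 1883 on day 2, 834 on day 3, 1757 on day 4 and 2465 on day 5, then 438 on day 6, 894 on day 7, 116 on day 8, 376 on day 9, 104 on day 10, 1073 on day 11 and 165 on day 12. In the severe course they numbered 7012 on day 1, 1616 on day 2, 3620 on day 3, 3134 on day 4, 1784 on day 5, 592 on day 6, 954 on day 7, 2325 on day 8, 2128 on day 9, 1735 on day 10, 3435 on day 11 and 1644 on day 12. With the library set taken out they numbered 5051 on day 1, 922 on day 2, 777 on day 6, 311 on day 7, 953 on day 8, 1158 on day 9, 224 on day 10, 2515 on day 11 and 311 on day 12. EdgeR on the 6 libraries of a day called 0 genes on moderate day 5 (3590 at an unadjusted p under 0.05, DESeq2 906), moderate day 10 (1946, DESeq2 368), severe day 4 (3365, DESeq2 1186) and severe day 5 (2792, DESeq2 588). It called 2 on day 6, 516 on day 7, 1 on day 8, 23 on day 9, 22 on day 11 and 4 on day 12 of the moderate course. In the severe course it called 4139 on day 1, 12 on day 6, 36 on day 7, 1434 on day 8, 466 on day 9, 90 on day 10 and 312 on day 12. On moderate days 1, 3 and 4 it called more genes, 4567, 2383 and 3314. Without replicate 3, edgeR called 0 on moderate day 5 (2898 at an unadjusted p under 0.05) and moderate day 10 (1343, DESeq2 on the 6 libraries 368), and without replicate 2 it called 0 on moderate day 12 (1124, DESeq2 on the 6 libraries 577). On day 6 of the severe course the replicate 3 libraries lay apart from the others of their arms, and 4109 genes were called without them. The rule for the onset, the day from which each day had at least 100 genes called, gave day 0 in both courses. The moderate counts on days 8 and 10 lay just above 100, and with dispersions estimated beforehand the moderate onset moved to day 11. With the library set taken out the severe onset moved to day 1. The moderate course had no onset day in 6 settings, and without 1 replicate number the severe onset ranged from day 0 to day 11.

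On day 0, 325 genes were higher and 583 lower in moderate drought than in its control, 908 in all. Of these, 206 also rose and 504 also fell on day 1, against 26 and 66 for independent lists. In severe drought on days 3-5, 200 of them also rose and 333 also fell, against 59 and 124. The arms of the moderate course thus differed at the start, and the later contrasts and shared counts are not adjusted for this. The day 0 drought library of replicate 2 was the library of its course in the higher library set, and without it 189 genes were called. Without all replicate 2 libraries 0 genes were called by edgeR, with 3048 at an unadjusted p under 0.05, and DESeq2 on the 6 libraries of that day called 1824. Day 0 of the severe course had 166 genes higher and 87 lower, 253 in all, and 22 were called with the library set taken out.

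Scores built in a course parted drought from control in the other. Each score was the mean, over 20 genes, of log2 CPM with the sign turned for the 10 genes that fell, and its genes were taken from days 9-12 of the other course. The score from the severe course was 0.79 ± 0.41 in moderate drought (SD, n = 12) and -0.49 ± 0.59 in moderate control (SD, n = 12) on days 9-12, a difference of 1.28 (permutation test within day, two-sided, p = 7e-05, adjusted over the 2 scores 7e-05). Drought lay above control on 4 of 4 days, and 10 of 12 drought libraries lay above the highest control. On day 10 the libraries of the arms overlapped, and on day 0 this score already differed by 0.54 between the moderate arms. The score from the moderate course was 1.53 ± 0.39 in severe drought (SD, n = 12) and -0.68 ± 0.34 in severe control (SD, n = 12), a difference of 2.21 (permutation test within day, two-sided, p = 2e-05, adjusted 4e-05). Here 12 of 12 drought libraries lay above the highest control, and the difference on day 0 was -0.06. The falling genes of the severe score included the 3 genes that mark the library sets, and with the set taken out the differences were 1.52 and 2.1.

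**Figure D4:**
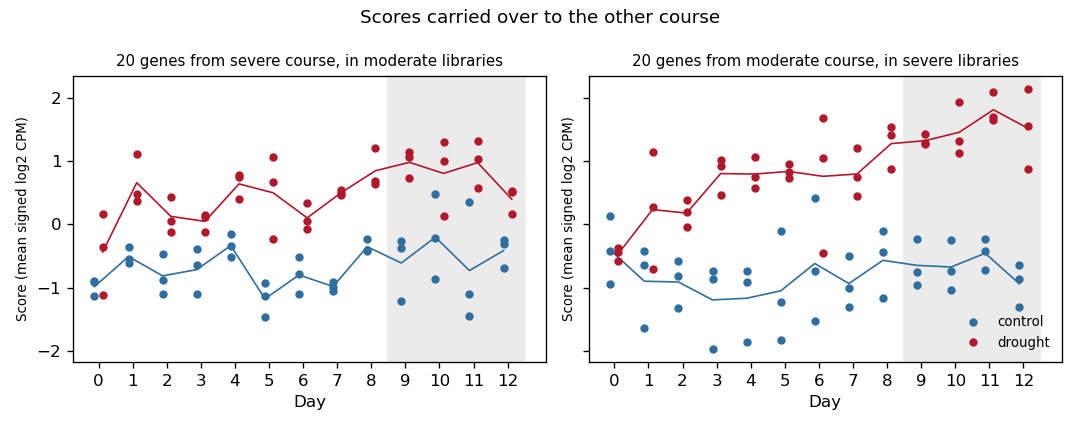
Score of each library (vertical axis, mean signed log2 CPM of 20 genes) by day (horizontal axis), for the score from the severe course in moderate libraries (left) and the score from the moderate course in severe libraries (right), with libraries as points and means of 3 as lines, control in blue and drought in red. The grey band marks days 9-12, where the drought minus control differences were 1.28 and 2.21.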

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

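The tests of the difference between the courses on days 1-4, 5-8 and 9-12 were planned, and the test of days 3-5, the late minus early tests, the splits and all tests of explanations were chosen after the results were seen. The difference between the courses was tested as an interaction, and it was called for 80 genes on days 1-4, 103 genes on days 5-8 and 2127 genes on days 9-12. The difference between days 9-12 and days 1-4 was called for 3801 genes in the moderate course and 8460 in the severe course. For late minus early, the 8 days were regrouped into 35 splits of 4 against 4 with each library kept in its arm, in an edgeR fit of the libraries compared only. The real split called 4906 genes and the highest other 1170 in the moderate course, and 7943 and 5942 in the severe course, 1 of 35 splits as large in each. The real split alone keeps the days of each stretch together. Any drift over the days, and in the severe course the change of library sets, therefore favours it. The splits cannot tell these from a change of the drought response. For the difference between the courses, the courses were exchanged on whole days, and the 8 splits (4 for days 3-5) are too few for a share under 0.05. The real and highest other counts were 85 and 284 on days 1-4 (3 of 8 splits as large), 71 and 69 on days 5-8, 1918 and 303 on days 9-12 (1 of 8 in each), and 22 and 0 on days 3-5 (1 of 4), the 0 with edgeR.

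The larger number of genes that differed between courses on days 9-12 may rest in part on the library sets, since severe control lay in the higher set and the other arms in the lower. Over the 235 genes at least 2-fold lower in the severe response the set difference followed the severity difference with a slope of 0.67 (0.58 from controls, 0.76 from drought libraries, 0.51 to 0.81 on log2 CPM without 1 replicate number), where 1 is expected if the set made it, and had the sign needed in 77% and 82.6% against 52.1% and 52.9% of all genes, while the median change moved from 1.49 (SE 0.39) to 0.70 (0.51) with the set taken out, 88.9% kept their sign and 21 their call. Over the other 1892 genes the slope was 0.06 (-0.02 and 0.14, and -0.12 to 0.26 without 1 replicate number), and the median change moved from 0.43 (SE 0.12) to 0.39 (0.15), which argues against the set as their whole cause, although only 452 were still called as the SE grew (526 and 11 with the estimate from controls or drought libraries alone). Thinning each library to the lowest depth left 1495 genes, which argues against depth. A stronger response of the raised pots stays open: the 4141 genes called alike in both courses on days 3-5 had a mean signed log2 change of 0.69 in the severe and 0.60 in the moderate course on those days, within a library set, and 0.18 and 0.28 on days 9-12, not adjusted for the set (difference of library means -0.11, permutation p = 0.26; -0.05 with the set taken out).

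The opposite early and late calls of the severe course, 2176 genes, may be a change of the drought response over the days that both courses share. In the moderate course, which lay in the lower set but for 1 library, 96.2% of these genes moved between the stretches in the same direction, against 77.8% of all genes tested, and 1425 of them were called in that direction there and 0 in the other. The 2176 genes were picked by large moves, so a share above that of all genes can come from the size of the moves alone. The library set as the whole source is argued against, since the late minus early difference of 69.2% of the 2176 genes was still called after it was taken out, although opposite calls then numbered 337 and 630. The moves were smaller in the moderate course, with medians of -0.31 and 0.47 on the log2 scale against -0.75 and 0.82. A drought response that depends on the age of the plants runs with the days of drying in both courses, so age stays open, and neither age nor soil water was tested.

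On day 6 of the severe course the 2 replicate 3 libraries lay out of place. The real split of the 6 libraries called 12 genes and the split with these libraries exchanged called 2762, while each other split called 0. An exchange of finished libraries or labels is argued against by the library set index, which was 6.65 in the control library and 2.98 in the drought library, each with its own arm, and also an exchange of leaves if the sets are plants of different genome. If the sets arose in library making, an exchange of leaves may account for the 2762 genes and cannot be told apart from unequal plants, since on genes of the moderate course the control library lay at 0.76 and the drought library at 0.27 of the way from the other controls to the other drought libraries. The replicate 3 controls of days 5, 7 and 8 lay at 0.71, 0.5 and 0.27 of that way, and the replicate 3 drought libraries of those days at 1, 0.93 and 0.89. An unequal response of single plants may account for this. Replicates 1 and 2 of each arm fix the scale on each day, so the replicate 3 values depend on those libraries, and other choices were not tested.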

How the results depend on the processing

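Gene list shifts were not run, since no list could be placed on the identifiers. Of 167 comparisons of 18 results with an alternative fixed beforehand, which include the 2 late minus early results added later, 114 kept their side of the threshold or stayed within 1.5 times the count, and 53 did not. Of the 53, 14 came from the 2-fold minimum, which can only lower a count. Leaving out replicate 1, 2 or 3, which also leaves fewer samples, gave 8, 12 and 8 of them. For the named genes 427 of 512 settings kept the call, 81 lost it and 4 turned the sign. For the daily counts 168 of 324 stayed within 1.5 times. The adjustments for the library set, the thinning, the dispersions estimated beforehand, the choice of days within 1 set and the late minus early contrasts were chosen after the data were seen. Where no construction shows why a value moved, the cause was not tested.

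Replicate numbers did not pair the samples: of 78 same-numbered pairs 13 correlated above 0.1 (median r -0.001), and 24 of 78 controls correlated best with their own number. With the replicate block 4795 genes were called in moderate drought on days 9-12 and 8759 in severe drought, and with the replicate block within day 4416 and 8451. For severity on days 1-4 the replicate block within day gave 39 genes, and 5 calls of named genes ended with it, that of LOC_Os01g72370 on moderate days 9-12 among them (adjusted p = 0.093).

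At least 2-fold, the counts were 165 and 113 on day 0, 770 and 1344 on days 1-4, 741 and 686 on days 5-8, 524 and 1227 on days 9-12, and 392 and 1994 for late minus early (moderate, then severe), 31, 63 and 291 for severity on days 1-4, 5-8 and 9-12, and 298 for shared calls. Without 1 replicate number, which also leaves fewer samples, the ranges were 0 to 189 (moderate day 0), 2971 to 4252 (days 5-8), 2611 to 3060 (days 9-12) and 1600 to 2785 (late minus early), and in the severe course 28 to 176 (day 0), 2213 to 6214 (days 5-8), 5465 to 7403 (days 9-12) and 5228 to 7481 (late minus early). For severity they were 6 to 56, 45 to 104 and 182 to 1348, for shared calls 1367 to 1832, and for the severe onset day 0 to 11. The moderate onset was day 11 without replicate 3, no such day came without replicate 1 or without replicate 2, and it stayed day 0 without the day 0 drought library of replicate 2 alone, which also gave the 189 on moderate day 0. The 0 is an edgeR count with 3048 genes at an unadjusted p under 0.05, and DESeq2 on the libraries of moderate day 0 called 1824.

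Without a filter on low counts moderate day 0 had 417 genes, severe day 0 had 135, and severity had 28 on days 1-4 and 1353 on days 9-12. DESeq2 on the libraries compared called 411 on severe day 0 and 229 for severity on days 1-4. EdgeR on the libraries compared called 6 on severe day 0 and 3492 on severe days 5-8, and moved the severe onset to day 11. Thinning left 121 on severe day 0 and 25 and 59 for severity on days 1-4 and 5-8. Dispersions estimated beforehand moved the moderate onset to day 11, and 6 settings gave the moderate course no onset day.

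With the library set taken out, severe drought had 22 genes on day 0 and 4403 on days 9-12, late minus early 4171, severity 189, 65 and 612, shared calls 1678, and the severe onset was day 1. With the set difference from controls alone severity had 264 on days 1-4 and 1303 on days 9-12, and from drought libraries alone 23, 48 and 11. For days 1-4 and 5-8 the adjustments shift weight between days, as described above. LOC_Os04g16874 turned to -0.09 and -0.68 for severity on days 1-4, and LOC_Os01g49370 to 0.35 and 0.88 on days 9-12, with the mean and the drought estimate. Days 3-4 alone gave 6104 in severe drought and 679 for severity. Day 5 alone gave 1784 in severe drought and 0 by edgeR for severity, with 1218 at an unadjusted p under 0.05. DESeq2 on the libraries of day 5 also called 0 for severity. On all of days 5-8 DESeq2 called 97 for severity, against 103 by edgeR in the main model.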

Other observations

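On days 9-12 of the severe course 1130 genes rose and 1453 fell that were called in neither direction on days 1-4, with a late minus early difference of the same sign. These groups of the moderate course held 289 and 397 genes. The severe response of days 5-8 lay closer to the late stretch, with r = 0.73 across genes against days 9-12 and 0.35 against days 1-4, where genes are not independent replicates. In the moderate course these were 0.70 and 0.61. The arms of the severe course lay in different library sets on days 6 to 12.

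The test of neighbouring identifiers and the split counts below were chosen after the data were seen. The genes that part the library sets lie together by identifier. Of 165 genes that differed at least 2-fold between the sets, 140 were higher in the higher set, and 70 had another of the 165 within 5 tested identifiers on the same chromosome. Random lists matched on expression had a median of 14 such genes and at most 36 in 10000 lists. Lists of the same size from moderate drought on days 9-12 and severe drought on days 3-5, with the largest fold changes, had 29 and 22. A candidate explanation for the 70 is that the plants of the sets differ in stretches of the genome, such as a second seed stock. A difference in library making could also move neighbours together where overlapping or opposite-strand genes share counts, and this was not tested. The median total was 11.2 M in the higher set and 17.1 M in the severe libraries of the lower set, so the sets also differ in depth. In sample order the 48 libraries of wholly higher groups form 1 unbroken run, from severe control day 3 to severe drought day 5. Such a run goes with a library batch, but the order itself follows arm and day. Seed stock and library batch cannot be told apart by these counts.

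The moderate drought library of day 0, replicate 2, lay at 0.74 of the way from the lower to the higher set on the 70 neighbouring genes and at 0.88 on the other 95. On the 70 genes it lay between the other libraries of the higher set (0.83 to 1.17) and the lower set (-0.16 to 0.44), and on the other 95 within the higher set (0.79 to 1.32). Its profile correlated across genes with its own group at r = 0.54, the highest of 52 groups, and next with r = 0.46.

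Shuffled arms within day, in an edgeR fit of the libraries compared only, gave a highest count of 4 genes on days 1-4, 3 on days 5-8 and 5 on days 9-12 of the moderate course, against 9144, 4674 and 4699 in the real split, 1 of 60 splits in each case. In the severe course the highest counts were 1841, 435 and 2932 against 8180, 3492 and 8052, again 1 of 60. Chance can therefore be excluded as the source of these counts. The arms of the severe course lay in different library sets on many of these days, and shuffling the arms also mixes the sets. For that course these splits cannot tell drought from the library set. Nor can they tell drought from a difference between the arms that was present on day 0. On days 3-5 the arms of each course shared a library set. There the highest other split called 0 genes in the moderate course and 1 in the severe course, against 6687 and 5850, 1 of 60 splits in each. On day 0 the 10 splits are too few for a share under 0.05, and the real split called 826 genes in the moderate and 6 in the severe course, with 0 as the highest other, 1 of 10 splits in each. Day by day, the real split called more genes than each other split on 8 of 12 days in the moderate course (highest other 97) and on 9 of 12 in the severe course (highest other 2762), and the 10 splits of a day are too few to exclude chance.

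Deviations from the group means had a leading axis with 15.4% of the variance within groups, which did not follow depth (r = 0.06, permutation p = 0.63). Of the variance of log2 CPM, 53.9% lay between groups.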
